A study of Homo sapiens with 6 samples.

How the data were processed

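Total RNA of HLE cells carrying a control shRNA or 1 of 2 ZNF281 shRNAs was sequenced in duplicate, 2 libraries in each of 3 groups. The submitters' processing notes name HISAT2 2.0.4, Bowtie2 2.2.5 and RSEM 1.2.12 and the builds GRCh38.p11 and hg38, with no role or order. The authors deposited 1 table of 21372 features by 6 libraries whose name speaks of gene counts, but its values are not whole numbers, are kept to 2 decimals and sum to between 512672.6 and 575886.9 per library. The deposited values were therefore taken as FPKM (fragments scaled to transcript length and to the library total), a unit that RSEM writes; this was inferred from the values and no label states it. No raw counts were used, so the depth is unknown and no counting interval is given. Comparing the smallest steps between low values across libraries put their relative depth between 0.998 and 1.047 of the first control library.

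The 19503 named genes were kept and 1869 features named BGI_novel were left out. Gene IDs were looked up in the RefSeq gene table for GRCh38.p14, where 19164 were found, 18007 with the same symbol. Coordinates, transcript lengths and 3' UTRs came from GENCODE release 29 on GRCh38, the longest coding transcript of each gene, and 10768 of the tested genes (99.2%) were matched.

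Before the data were examined, a test for counts was planned and another was listed as an alternative; neither was used, because the values are not counts. Instead, log2(FPKM + 0.1) of genes at 1 FPKM or more in at least 2 libraries (10851) was fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 6 libraries, an intensity trend and robust moderation (3 residual degrees of freedom, median 8.64 after moderation). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within each contrast: kd.1 against control, kd.2 against control, kd.2 against kd.1, and the mean of both knockdowns against control. SDs are over 2 libraries and SEs are from limma. With 2 libraries per group an exact permutation test of single values could not reach 0.05, so none is given. Fold changes are ratios on the log2(FPKM + 0.1) scale.

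Before the data were examined, 32 gene lists were fixed: epithelial junction and keratin genes, mesenchymal and EMT genes, collagens and laminins, matrix proteases and inhibitors, integrins, annexins, NuRD complex, hepatocyte genes, S phase and replication genes, G2 and mitosis genes, p53 target genes, DNA repair genes, interferon response genes, NF-kB and inflammatory genes, unfolded protein and amino acid stress genes, glycolysis and hypoxia genes, cholesterol synthesis genes, fatty acid synthesis genes, WNT target genes, TGF-beta and BMP target genes, YAP target genes, NRF2 target genes, pluripotency and stem cell genes, cytosolic ribosomal proteins, mitochondrially encoded genes, replication-dependent histones, and fibroblast, endothelial, leukocyte, erythroid, neuronal and squamous keratinocyte markers. The 24 lists with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists within a contrast. Camera compares a list with the other genes. No list call held with an estimated correlation. In that setting camera takes its p from the 3 residual degrees of freedom, whereas the preset uses a number set by the genes. With so few, hardly any list could be called, so such a loss decides neither for nor against a list. The mesenchymal and EMT genes lost theirs at an estimate of -0.0706, below the preset. The loss therefore does not show that correlation between members explains the calls. Fry, which asks whether a list's genes moved on balance 1 way, was an alternative.

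The genes named in the text were set by a rule fixed before the data were examined. They are ZNF281, ZNF148 and ANXA10; the 10 risen and 10 fallen genes called in both lines with the largest smaller change of the 2 and all knockdown libraries beyond both controls; 5 risen and 5 fallen genes for each shRNA and for kd.2 against kd.1 by size of change, with libraries not overlapping; and up to 4 members per list with the smallest p in the mean contrast. The planned minimum of 100 mean normalised counts was replaced by a mean of 1 FPKM. Some genes that the rule names are not reported here.

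Both contrasts against control share the control libraries. For shared controls where neither line changes, unchanged groups were simulated from the spread between duplicates and set against shared simulated controls (50 draws). In addition, chosen after the data were seen, each line was set against a different control library. For 3' UTR sequence, each of 16158 heptamers (7 bases) was scored in 10579 genes with a 3' UTR of at least 50 bases by a z for the fold changes of carriers clipped at 2 log2 units, after removal of trends on UTR length and GC content, in heptamers held by at least 50 genes, and 100 shuffles of genes gave extremes; this was chosen after the gene-level results were seen. The fit was tested on simulated data for kd.1 against control (10851 genes, 200 changed, 10 runs). It recovered 90.1% of genes changed 1.5-fold, 98.5% changed 2-fold and 99.5% changed 4-fold, and 10.78% of its calls were false, above the 5% aimed at; the simulated groups differed in spread as the measured ones did. In simulated lists for both shRNAs against control the raised list was called in 100% of runs and 1 of 200 unchanged lists was called. The simulated genes varied independently, so this rate does not cover lists whose members vary together. The estimated correlation was 0.914 in the cytosolic ribosomal proteins.

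Alternatives were median-of-ratios scaling, no filter on low values, only the libraries of the 2 groups compared, each library left out in turn, a fold minimum of 2, a replicate block, fry and an estimated correlation. Pseudocounts of 1 and 0.01, a common FPKM sum, the BGI_novel features kept, removal of a trend on transcript length and lists without heptamer carriers were added after seeing the data. Calculations outside limma used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.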

Results

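RNA was sequenced from HLE cells, an undifferentiated human hepatocellular carcinoma line, carrying lentiviral short hairpin RNAs (shRNAs). ZNF281 is a zinc-finger transcription factor. Lines were made with a control shRNA or with 1 of 2 shRNAs against different coding sites of ZNF281 (kd.1 and kd.2), infected at a multiplicity of 10 and kept in puromycin for 7 days. Each of the 3 lines gave 2 libraries, 6 in all. The deposited table gives FPKM per gene, so the absolute sequencing depth is unknown. Its columns summed to between 512672.6 and 575886.9 FPKM, and the steps between low values put the libraries within 0.998 to 1.047 times the depth of the first control library. Of the 19503 named genes, 10851 reached 1 FPKM in at least 2 libraries and were tested. Over these genes, the SD of the log2 difference between duplicates was 0.147 in kd.1, 0.137 in kd.2 and 0.245 in the control. The first principal component held 46.7% of the variance and separated kd.1 from kd.2, and the second held 39.5% and separated the kd.1 libraries from the controls. The labels do not say whether duplicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

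The first question was whether the targeted transcript was lower in each knockdown line. ZNF281 (gene ID 23528; GRCh38, chromosome 1, 200404940 to 200410056, minus strand, coding sequence of 2685 bases before the stop codon) stood at 8.98 ± 0.77 FPKM in the control (SD, n = 2), 4.53 ± 0.25 in kd.1 and 4.42 ± 0.07 in kd.2. The knockdown means were 50.5% and 49.2% of the control mean. All 4 knockdown libraries, at 4.35, 4.71, 4.37 and 4.47 FPKM, lay below both controls, at 9.52 and 8.43. The log2 fold change was -0.97 ± 0.09 (SE) in kd.1 (limma, adjusted p = 0.000249) and -1.0 ± 0.09 in kd.2 (adjusted p = 0.00024), and the lines did not differ detectably from each other (difference -0.03 ± 0.09, adjusted p = 0.805). ZNF148 (gene ID 7707), the closest paralog of ZNF281, rose from 5.14 ± 0.56 to 6.66 ± 0.05 FPKM in kd.1 and to 6.62 ± 0.08 in kd.2 (adjusted p = 0.0191 and 0.0173). Each ZNF148 call was lost when either library of its own knockdown line was left out (adjusted p = 0.107 and 0.101 in kd.1, 0.113 and 0.0943 in kd.2), and the 3' UTR of ZNF148 carries GAAGTCA and TCAGAGT, heptamers described below. ANXA10 (gene ID 11199; chromosome 4, 168092515 to 168187690), an annexin that binds calcium and phospholipid, was near the floor in the control (0.20 ± 0.04 FPKM) and rose to 3.37 ± 0.27 in kd.1 and 1.04 ± 0.15 in kd.2. On the log2(FPKM + 0.1) scale, which is used for every fold change here and understates those of low genes, the ANXA10 change was 3.51 ± 0.16 in kd.1 and 1.91 ± 0.16 in kd.2 (adjusted p = 9e-06 and 0.000176).

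**Figure D1:**
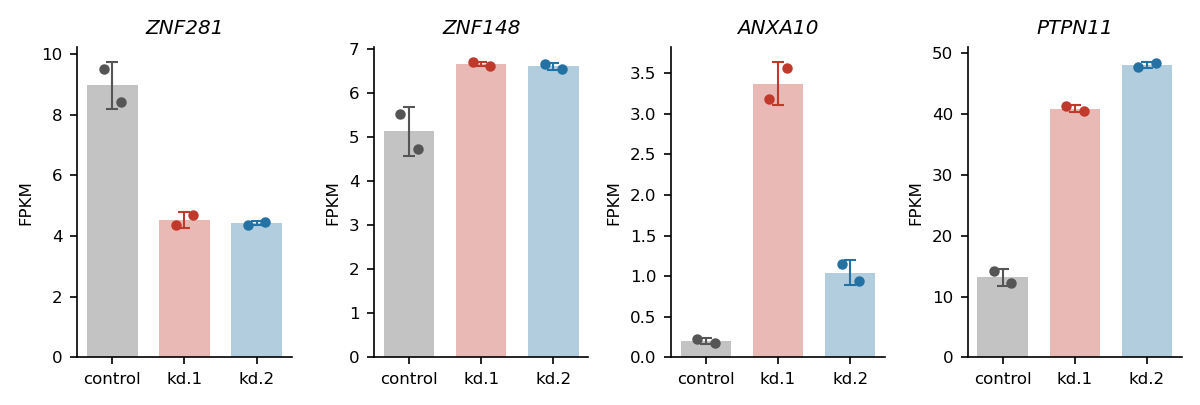
FPKM of ZNF281, ZNF148, ANXA10 and PTPN11 in the control, kd.1 and kd.2 lines; bars are means of 2 libraries, points are the libraries and error bars are the SD. ZNF281 falls from 8.98 to 4.53 and 4.42 FPKM, and PTPN11 rises from 13.2 to 40.9 and 48.1 FPKM.

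Genes changed the same way by both shRNAs were examined next. PTPN11, which encodes the tyrosine phosphatase SHP2, rose 3.09-fold in kd.1 and 3.64-fold in kd.2, from 13.2 ± 1.4 to 40.9 ± 0.6 and 48.1 ± 0.5 FPKM. TFAM, the mitochondrial transcription and packaging factor, rose 2.49-fold and 3.10-fold from 14.4 ± 2.4 FPKM. SOAT1, which esterifies cholesterol, rose 2.82-fold and 2.30-fold from 16.8 ± 5.0 FPKM, and SLC44A1, a choline transporter, rose 2.33-fold and 2.26-fold from 2.34 ± 0.45 FPKM. MBLAC2, the nuclear receptor NR4A3, the collagen receptor subunit ITGA1, the readthrough transcript GPR75-ASB3, FRRS1 and ANXA10 completed the 10 named risen genes, with changes of at least 0.94 on the log2 scale in each line. GPR75-ASB3 shares its reads with GPR75 and ASB3, so its level is uncertain; its call was lost without kd.1 replicate 2 (adjusted p = 0.0723), kd.2 replicate 1 (0.0928) or kd.2 replicate 2 (0.0554), and that of NR4A3 in kd.2 without kd.2 replicate 2 (0.0748). The heptamer TCAGAGT lies in the 3' UTR of 5 of these 10 genes: PTPN11 has 1 site, and TFAM, SLC44A1, MBLAC2 and ITGA1 have 2 each. GAAGTCA lies in PTPN11 and ITGA1, and CTCAGAA in PTPN11, SOAT1 and SLC44A1, the last with 4 sites. Of the 8 named fallen genes searched, 1 (ZBED6CL) carries TCAGAGT and 0 carry the others. These counts are not corrected for UTR length.

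Among genes lower in both lines, the small heat shock protein gene CRYAB fell 3.53-fold in kd.1 and 5.82-fold in kd.2, from 2.76 ± 0.59 to 0.70 ± 0.03 and 0.38 ± 0.01 FPKM. SNCG, which encodes gamma-synuclein, fell 2.57-fold and 3.44-fold from 226 ± 29 FPKM. The contractile regulator MYLK fell 2.59-fold and 2.5-fold from 6.43 ± 0.42 FPKM, and CDH5, the cadherin of endothelial junctions, fell 2.5-fold and 2.61-fold from 2.14 ± 0.40 FPKM. LCN2, an iron-carrier binding protein of the acute phase, fell 2.56-fold and 2.39-fold from 39.4 ± 2.9 FPKM. UPK3B, ZBED6CL, CRIP2, TOX2 and HOTS were the others, with changes between -1.1 and -2.35 on the log2 scale; HOTS overlaps H19 on the opposite strand, so its level is uncertain where strand was not counted. The largest adjusted p among these 10 genes, in limma, was 0.00371 (CDH5 in kd.1).

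In total 1398 genes were called in both lines with the same sign, 701 up and 697 down, against 591.3 for independent lists of these sizes. Another 233 genes were called with opposite signs (607.9 for independent lists). Unchanged groups simulated against the same controls shared on average 0.28 calls (50 draws). They gave on average only 0.72 calls in kd.1 and 0.6 in kd.2, so hardly any could be shared. How many of the 1398 come from the shared controls cannot be told from this, and 591.3 takes no account of those controls. The correlation of fold changes across genes, which are not independent replicates, was 0.439, below the 0.747 that the shared controls gave with no effect (0.689 to 0.801); the covariance was 0.053 against a simulated 0.0122, a difference of 0.0409. With each line set against a different control library, so that none was shared, the covariance was 0.0336 and 0.0424 for the pair of ways to do so. Both control libraries come from 1 control line, so a trait of that line or its shRNA stays in both contrasts. The covariance was 0.102 without control replicate 1 and 0.0344 without control replicate 2. The shared count was 3552 without control replicate 1, 573 and 594 without kd.1 replicate 1 and 2, 469 and 490 without kd.2 replicate 1 and 2, and 909 with no filter; with a common FPKM sum it was 855 up and 342 down.

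TCAGAGT lay in the 3' UTR of 29.9% of the 696 searched genes risen in both lines, 6.2% of the 678 fallen in both and 12.2% of the other 9205. These shares are not corrected for UTR length, and longer UTRs hold more of any heptamer. With UTR length and GC content removed, genes with 1 site stood above genes with 0 by a median log2 change of 0.054 in kd.1 and 0.03 in kd.2. Genes with 2 or more sites stood above them by 0.087 and 0.037. TCAGAGT had the highest z of the heptamers in both lines, 6.09 in kd.1 and 5.04 in kd.2. The highest of 100 shuffles reached 5.28 and 4.86. Between the control duplicates, where no shRNA differs, GGCTAAT reached a z of 7.23 (highest shuffle 4.84). The shuffles can thus be passed without an shRNA difference, and the TCAGAGT z alone is weak evidence. Several of the highest heptamers there overlap each other, such as GGCTAAT, CGGCTAA (6.84) and GCTAATT (6.69). TCAGAGT was not among the highest there, so 7.23 is not a measured limit for its own z.

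**Figure D2:**
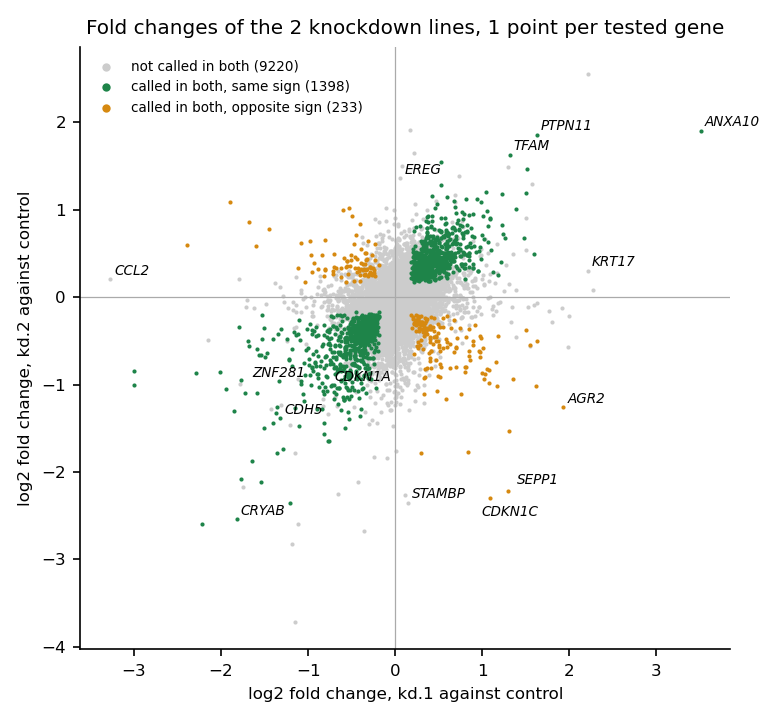
Log2 fold change against control in kd.1 (horizontal axis) and in kd.2 (vertical axis), each point a tested gene on the log2(FPKM + 0.1) scale. Green marks 1398 genes called in both lines with the same sign and orange 233 called with opposite signs; CCL2 and KRT17 lie far out on the kd.1 axis and STAMBP on the kd.2 axis.

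Targets of the tumour suppressor p53 were lower in both lines. CDKN1A, the p21 cell cycle inhibitor, fell from 40.7 ± 4.5 FPKM to 23.6 ± 3.3 in kd.1 and 21.6 ± 0.9 in kd.2. MDM2, a ubiquitin ligase that carries GAAGTCA, fell from 14.5 ± 0.5 to 8.85 ± 0.67 and 6.77 ± 0.64. The apoptosis gene BAX fell from 92.6 ± 8.4 to 54.4 ± 2.6 and 64.3 ± 1.4 FPKM, and DDB2, a DNA damage sensor, from 27.9 ± 1.0 to 20.5 ± 0.7 and 14.5 ± 0.2. Over both shRNAs, 10 of the 20 tested members fell, 0 rose and 10 did not pass (14 fell adjusted over the list alone), with a median log2 change of -0.37. In kd.1 alone 12 fell and 0 rose, and in kd.2 12 fell and 1 rose. The list test, limma's camera with a preset correlation of 0.01, gave adjusted p = 2.44e-05 over both, 5.45e-06 in kd.1 and 0.0017 in kd.2. With an estimated correlation the adjusted p values were 0.531, 0.536 and 0.712.

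Among mesenchymal and EMT genes, smooth muscle actin ACTA2 fell from 5.40 ± 0.42 FPKM to 2.89 ± 0.02 in kd.1 and 2.61 ± 0.28 in kd.2, and the actin-binding TAGLN fell 1.54-fold over both lines from 2.75 ± 0.11. TWIST1, a transcription factor of the mesenchymal programme, fell 1.43-fold over both lines. TGFBI, a TGF-beta-induced matrix protein, was 20.8 ± 1.1 in the control and 20.2 ± 0.4 in kd.1 and fell to 9.01 ± 0.34 in kd.2. Over both shRNAs 7 of 12 tested members fell, 1 rose and 4 did not pass (8 fell and 1 rose adjusted over the list alone), with a list adjusted p of 0.0352. That call was lost with an estimated correlation (adjusted p = 0.531) and without control replicate 1 (0.118). SNAI2, also of this list, rose in kd.1 and fell in kd.2, as given under other observations. FN1 and 9 other members did not reach the filter.

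The epithelial junction and keratin genes split. MUC1, a membrane mucin, fell 1.71-fold over both lines from 142 ± 14 FPKM, and the tight junction gene CLDN4 fell 1.51-fold over both lines. KRT8 and KRT18, the paired keratins of simple epithelia, fell 2.12-fold and 2.20-fold in kd.1, from 1312 ± 4 and 1151 ± 39 FPKM, and stood 1.12-fold lower in kd.2, where neither passed (adjusted p = 0.129 and 0.134). Of 17 tested members 5 rose, 6 fell and 6 did not pass over both shRNAs, with the same counts adjusted over the list alone and no call of the list (adjusted p = 0.881); the median was 0.04, the mean -0.06 and the test's direction down. In kd.1 the median was 0.28 with 8 up and 5 down, and in kd.2 it was -0.17 with 2 up and 7 down. CLDN7, also of this list, stood above control in kd.1 and below it in kd.2, as given under other observations. CDH1 and EPCAM stayed at or below 0.07 FPKM in every library.

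Of the adhesion and matrix lists, none was called over both shRNAs. The collagen receptor subunits ITGA1 and ITGA2 rose, ITGA1 from 5.31 ± 1.73 FPKM to 10.4 ± 0.2 and 11.2 ± 0.1 and ITGA2 1.83-fold over both lines, while 8 of 10 integrins did not pass (list adjusted p = 0.538). ITGA2 carries CTCAGAA and TCAGAGT in its 3' UTR. In the collagens and laminins, 4 of 15 rose and 1 fell: the laminin chain gene LAMA3 rose 2.21-fold in kd.1, LAMB3 rose 1.33-fold in both lines and the anchoring collagen COL7A1 fell 1.47-fold over both (list adjusted p = 0.538). In the matrix proteases and inhibitors 3 of 14 rose and 5 fell (4 and 7 adjusted over the list alone; list adjusted p = 0.599), with 2 up and 7 down in kd.1 and 6 up and 3 down in kd.2; the inhibitor TIMP3 fell 1.76-fold in kd.1 and stood 1.19-fold above control in kd.2. The membrane protease MMP24 fell 1.76-fold and 2.71-fold. The inhibitor TIMP2, which carries CTCAGAA, fell 1.4-fold over both lines from 92.7 ± 11.6 FPKM. Among other annexins, ANXA8 fell from 37.1 ± 1.9 FPKM to 27.3 ± 0.4 and 20 ± 0.7. ANXA4, which carries CTCAGAA, fell 1.52-fold in kd.2. Of 12 annexins 1 rose and 5 fell (2 and 5 adjusted over the list alone; list adjusted p = 0.524), with a median of -0.07, a mean of 0.07 and a test direction of down. ANXA8 and ANXA8L1 are near-identical copies and their levels are uncertain. Counts adjusted over the list alone were the same as over all genes for integrins, collagens and laminins.

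Several genes of the unfolded protein and amino acid stress list rose. SLC7A11, the cystine importer, rose 1.96-fold over both lines from 10.9 ± 0.5 FPKM, and asparagine synthetase ASNS rose 1.56-fold from 40.5 ± 3.0; SLC7A11 carries CTCAGAA 2 times. XBP1, a transcription factor of the unfolded protein response, rose from 80.2 ± 0.7 to 116 ± 2 and 109 ± 1. PHGDH, the entry enzyme of serine synthesis, rose 2.04-fold in kd.1 and was 1.1-fold above control in kd.2 (adjusted p = 0.12). Of 21 tested members 9 rose, 1 fell and 11 did not pass over both shRNAs (10 and 1 adjusted over the list alone), with a list adjusted p of 0.00219, and of 0.006 in kd.1 and 0.0207 in kd.2. With an estimated correlation the adjusted p values were 0.531, 0.536 and 0.712, and without control replicate 1 they were 0.0865, 0.0542 and 0.182.

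The NRF2 target genes, which respond to oxidants, overlapped that list at SLC7A11. TXNRD1, thioredoxin reductase, rose 1.56-fold over both lines from 178 ± 21 FPKM, and GCLM, a subunit of the glutathione synthesis enzyme, rose 1.38-fold from 12.1 ± 0.7. Over both shRNAs 7 of 17 rose and 0 fell (8 rose adjusted over the list alone; list adjusted p = 0.0352); in kd.1 10 rose and 1 fell (11 and 1 adjusted over the list alone; adjusted p = 0.000498), and in kd.2 4 rose and 2 fell (adjusted p = 0.557). With an estimated correlation the adjusted p values over both and in kd.1 were 0.926 and 0.683, and with fry 0.324 and 0.139. The call over both was also lost without kd.1 replicate 1 (0.0953), kd.2 replicate 1 (0.0638), control replicate 1 (0.315) or the members carrying 1 of the 3 heptamers (0.35), and the TXNRD1 and GCLM calls over both without control replicate 2 (0.104 and 0.0939). TXNRD1 carries GAAGTCA and GCLM TCAGAGT.

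**Figure D3:**
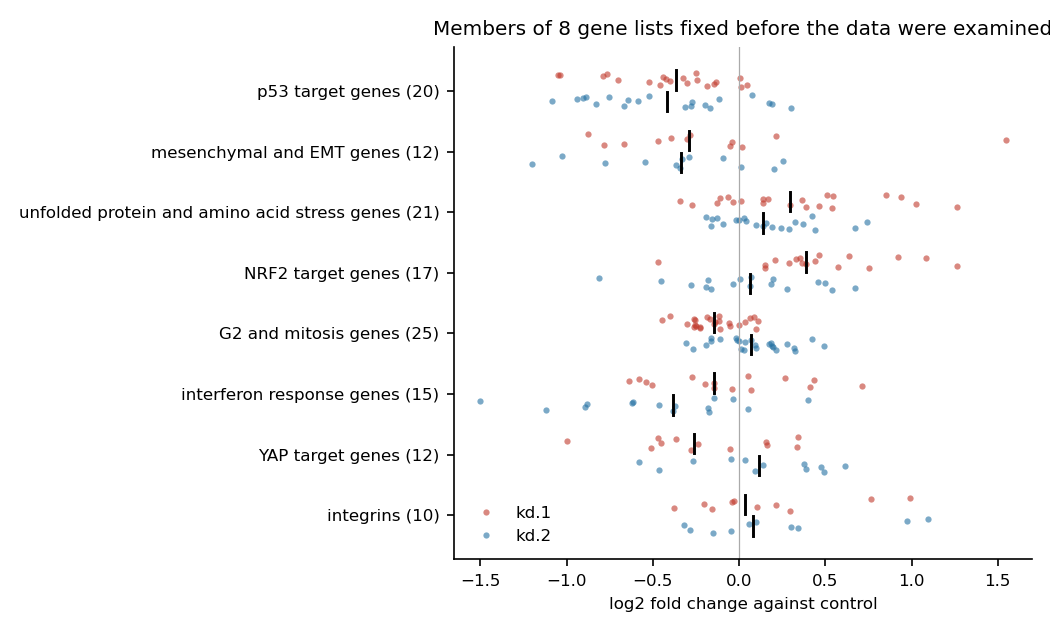
Log2 fold change against control of each tested member of 8 gene lists, with kd.1 in red and kd.2 in blue; black ticks are list medians, and the number of tested members stands after each name. The p53 target genes have medians of -0.36 in kd.1 and -0.42 in kd.2, whereas the G2 and mitosis medians are -0.14 and 0.07.

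Proliferation genes were examined next. PCNA, the replication clamp, fell from 393 ± 8 FPKM to 282 ± 8 in kd.1 and 282 ± 1 in kd.2, and thymidylate synthase TYMS from 191 ± 5 to 147 ± 1 and 138 ± 0.4. RFC4 and UHRF1, both of replication, fell 1.52-fold and 1.5-fold in kd.2; UHRF1 carries GAAGTCA and CTCAGAA. Over both shRNAs 7 of 25 S phase and replication genes fell and 1 rose, also adjusted over the list alone (list adjusted p = 0.146). In kd.2, 9 fell and 0 rose, again also adjusted over the list alone (adjusted p = 0.0358, and 0.83 with an estimated correlation); that call was lost without kd.2 replicate 2 (0.064), without control replicate 1 (0.208) and with a common FPKM sum (0.0827). Of 25 G2 and mitosis genes, 10 fell and 0 rose in kd.1, also adjusted over the list alone (adjusted p = 0.00137, and 0.593 with an estimated correlation). Cyclin B2 CCNB2 fell there from 76.1 ± 1.2 to 55.9 ± 0.4 FPKM and the mitotic kinase AURKB from 66.5 ± 6.35 to 50.2 ± 0.9. Over both shRNAs 3 rose and 4 fell (1 and 4 adjusted over the list alone; adjusted p = 0.599). In the DNA repair genes 5 of 26 rose and 4 fell, also adjusted over the list alone (adjusted p = 0.881): DNA ligase LIG1 fell 1.29-fold and the damage kinase ATM rose 1.31-fold over both lines.

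Chromatin and ribosome lists followed. The NuRD complex, a histone deacetylase and remodelling complex, had 5 of 14 members down and 0 up over both shRNAs, also adjusted over the list alone (list adjusted p = 0.242). HDAC1 fell 1.23-fold over both lines from 84.2 ± 2.1 FPKM, and MTA2, which carries CTCAGAA, fell 1.60-fold in kd.2. In kd.1, 2 NuRD members fell and 0 rose, also adjusted over the list alone (adjusted p = 0.0476, and 0.536 with an estimated correlation), a call lost without any 1 library other than control replicate 2 (0.0533 to 0.141), with a common FPKM sum (0.123) and without the heptamer carriers (0.122). Of 12 replication-dependent histones, 6 rose and 0 fell in kd.1 (adjusted p = 0.02, and 0.655 with an estimated correlation). That call was also lost with a replicate block and without control replicate 1. Over both shRNAs 5 histones rose (adjusted p = 0.15), and these counts were the same adjusted over the list alone. HIST1H4H rose 1.92-fold and HIST1H2AC 1.39-fold over both. In kd.2 their median and mean were -0.10 and -0.09 while the test's direction was up. In the cytosolic ribosomal proteins 11 of 38 fell and 0 rose over both shRNAs (10 fell adjusted over the list alone), with a median of -0.20 and list adjusted p = 0.0001 (0.000498 in kd.1, 0.00162 in kd.2). With an estimated correlation these were 0.926, 0.705 and 0.83, and with fry 0.189, 0.285 and 0.175. Removal of a trend on transcript length took the p values to 0.145, 0.108 and 0.217, and in kd.1 the call was lost without control replicate 2 (0.129). Control replicate 2 was higher than replicate 1 by a median of 0.21 log2 units in the shortest 10% of transcripts and lower by 0.19 in the longest (Spearman -0.567 with length across genes, against 0.011 in kd.1 and 0.115 in kd.2).

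Interferon response genes were lower in kd.2. IFI6 fell from 3.17 ± 0.23 FPKM to 1.06 ± 0.09, ISG15, a ubiquitin-like modifier, from 13.2 ± 2.9 to 6.96 ± 0.28, and OASL from 3.50 ± 0.42 to 1.55 ± 0.06; IFIT1 fell 1.55-fold in kd.1 and 1.54-fold in kd.2. In kd.2, 9 of 15 tested members fell and 1 rose (10 and 1 adjusted over the list alone; list adjusted p = 0.0145, and 0.712 with an estimated correlation), a call lost without control replicate 1 (0.135). Over both shRNAs 6 fell and 2 rose (8 and 2 adjusted over the list alone; adjusted p = 0.146). The NF-kB and inflammatory genes were mixed, with 3 of 13 up and 3 down over both, also adjusted over the list alone (adjusted p = 0.617). PTGS2, the inducible cyclooxygenase, rose from 13.9 ± 3.1 to 23.5 ± 0.1 and 24.3 ± 1.4 FPKM; its 3' UTR carries GAAGTCA and TCAGAGT. The chemokine CCL2 fell in kd.1, and NFKBIA, an inhibitor of NF-kB, fell 1.38-fold there. In kd.2 the median of this list was 0.05 and its mean -0.05.

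Metabolic lists were not called over both shRNAs. Of 23 glycolysis and hypoxia genes 5 rose and 5 fell (adjusted p = 0.897): EGLN3, an oxygen-sensing hydroxylase that carries GAAGTCA and CTCAGAA, fell 1.58-fold over both lines from 15.2 ± 0.5 FPKM, and VEGFA fell 1.28-fold. Among 21 cholesterol synthesis genes 1 rose and 4 fell (adjusted p = 0.257), and in kd.2 8 fell and 1 rose, also adjusted over the list alone (adjusted p = 0.0805). MVD of the mevalonate pathway fell 1.48-fold in kd.2. Of 11 fatty acid synthesis genes 3 rose and 1 fell (adjusted p = 0.312): the desaturase SCD rose 1.31-fold over both lines and ACSS2, which makes acetyl-CoA and carries CTCAGAA, fell 1.51-fold. All 3 counts over both shRNAs were the same adjusted over the list alone.

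Signalling lists were not called over both shRNAs either. Of 5 tested WNT target genes 1 rose and 2 fell (adjusted p = 0.892; median 0.08, mean -0.0026), and cyclin D1 CCND1, a carrier of GAAGTCA, fell from 21 ± 1.4 FPKM to 10.7 ± 0.02 in kd.1 and rose to 29.4 ± 1.3 in kd.2. MYC was 100 ± 0.4 in the control and 102 ± 5 in kd.1 and rose to 142 ± 7 in kd.2. Of 10 TGF-beta and BMP target genes 2 rose and 2 fell (adjusted p = 0.881): BAMBI, a decoy receptor, fell from 8.02 ± 0.69 to 3.95 ± 0.33 in kd.2, and the cell cycle inhibitor CDKN2B, with a GAAGTCA site, rose 1.74-fold in kd.1. Of 12 YAP target genes 4 rose and 4 fell (adjusted p = 0.897; median 0.06, mean -0.05), and AXL, a receptor tyrosine kinase that carries TCAGAGT, fell from 16.1 ± 0.4 to 8.04 ± 0.33 and 10.8 ± 0.3. These 3 counts were the same adjusted over the list alone.

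Lineage lists were mostly silent in this line. Of 26 hepatocyte genes 4 reached the filter, and 0 were called over both lines. HNF4A, a hepatocyte transcription factor that carries all 3 heptamers, rose from 0.57 ± 0.04 to 1.18 ± 0.04 FPKM in kd.1 (limma, adjusted p = 0.00327). RBP4 rose in kd.1 (limma, adjusted p = 0.0348) and fell in kd.2 (0.00584). FOXA1 fell in kd.2 (limma, adjusted p = 0.0247), and SERPINA1 was called in neither line. Of 5 tested fibroblast markers 2 fell and 0 rose over both (1 and 2 rose and fell adjusted over the list alone; list adjusted p = 0.617), with FBLN1 at 200 ± 4, 170 ± 12 and 138 ± 4 FPKM and decorin DCN, with 2 GAAGTCA sites, at 72.9 ± 0.5, 92.3 ± 8.8 and 38.3 ± 0.5. Lists with under 5 tested members had no list test, and their calls here are over both shRNAs. Of 4 tested endothelial markers CDH5 and EGFL7 fell. Of 4 tested pluripotency and stem cell genes BMI1 rose, but not when adjusted over the list alone. Of 2 tested leukocyte markers CD68 rose, and of 2 tested erythroid markers none was called. The 2 tested neuronal markers, TUBB3 and SNAP25, fell on average, but each was called in 1 line alone. TUBB3 was called in kd.1 (log2 change -0.65, against 0.02 in kd.2) and SNAP25 in kd.2 (-0.98, against 0.15 in kd.1). Of 3 tested squamous keratinocyte markers KRT17 rose, called in kd.1 alone, and KRT15 fell, called in kd.2 alone. The BMI1 call was lost without any 1 library other than control replicate 1 (0.0956 to 0.174). The SNAP25 call was lost without kd.1 replicate 1 (0.0721), kd.2 replicate 1 (0.0514) or kd.2 replicate 2 (0.0729), and that of KRT15 without kd.1 replicate 1 (0.0832), kd.2 replicate 1 (0.101), kd.2 replicate 2 (0.0548) or control replicate 2 (0.184). The mitochondrially encoded genes had 0 members in the table.

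Each shRNA was then compared with the control. In kd.1, KRT17, a keratin of basal and stressed epithelia, rose 4.62-fold from 219 ± 8 to 1020 ± 182 FPKM. AGR2, a secretory pathway protein disulfide isomerase, rose 3.81-fold from 1.23 ± 0.08. The collagen COL15A1 and the WNT receptor FZD10 rose 3.48-fold and 3.40-fold, and FZD10 carries CTCAGAA 2 times. TRIM31, a ubiquitin ligase, rose 3.96-fold to 24.2 ± 9.4, a call lost without control replicate 2 (adjusted p = 0.0604). The chemokine CCL2 fell from 4.60 ± 0.93 to 0.38 ± 0.09 FPKM (9.68-fold), the acute-phase gene SAA1 7.97-fold from 4.65 ± 1.37, the carboxypeptidase CPA4 7.97-fold from 39.2 ± 3.4, the Toll-like receptor relative CD180 5.25-fold from 1.31 ± 0.07 and the calcium-binding CALB2 4.89-fold from 6.62 ± 0.62. In all, limma called 3166 of 10851 genes, 1712 up and 1454 down, of which 78 rose and 89 fell at least 2-fold. Carriers of GAAGTCA, the heptamer with the lowest z in kd.1 (-11.66, lowest of 100 shuffles -4.54), were called down in 20.6% of cases against 13.4% of genes with none of the 3 heptamers. Neither share is corrected for UTR length. The count was 2015 with only the 4 libraries of these 2 groups, 1294 to 2007 without any 1 knockdown library and 5531 without control replicate 1, and with a common FPKM sum the split was 1889 up and 847 down.

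In kd.2, EPGN and EREG, neighbouring epidermal growth factor ligands on chromosome 4, rose 2.91-fold and 2.57-fold from 5.65 ± 0.92 and 11 ± 2.2 FPKM, PLSCR4, a scramblase family member, rose 2.83-fold, and RGS2, a G protein regulator, rose 2.43-fold from 38.6 ± 0.3. STAMBP, a deubiquitinase, fell 5.10-fold from 17.6 ± 0.5 to 3.36 ± 0.13 FPKM, and its 3' UTR carries CTCAGAA 4 times and GAAGTCA and TCAGAGT 1 time each; RGS2, which rose, also carries CTCAGAA. CDKN1C, the p57 cell cycle inhibitor, fell 4.91-fold from 7.62 ± 1.56, the actin bundler ESPN 4.8-fold from 2.24 ± 0.32, the selenium carrier SEPP1 4.64-fold from 3.98 ± 0.15 and RGS19, which carries CTCAGAA 2 times, 3.58-fold from 15.1 ± 0.8. Here limma called 4110 genes, 1705 up and 2405 down, of which 31 rose and 133 fell at least 2-fold. CTCAGAA had the lowest z in kd.2 (-11.16, lowest shuffle -5.23). Of its carriers 24.6% were called down, against 23% of genes with none of the 3. These shares are not corrected for UTR length, and carriers of GAAGTCA and TCAGAGT were called down in 16.8% and 13.5% of cases. With UTR length and GC content removed, the median log2 shift against genes with 0 CTCAGAA sites was -0.08 with 1 site and -0.115 with 2 or more. The count was 1282 and 1481 without kd.2 replicate 1 and 2 and 6175 without control replicate 1, and with a common FPKM sum the split was 2122 up and 1339 down.

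The lines were compared directly to ask where the shRNAs differed. SEPP1 and CDKN1C rose 2.46-fold and 2.12-fold in kd.1 and fell in kd.2, so that kd.2 lay 11.42-fold and 10.42-fold below kd.1. AGR2 (9.13-fold), NCCRP1 (7.19-fold) and the membrane protein FXYD3 (6.20-fold) were also lower in kd.2, each above control in kd.1 and below it in kd.2. CCL2 (11.17-fold), CD180 (7.95-fold), tissue plasminogen activator PLAT (7.93-fold), the cholesterol ester hydrolase NCEH1 (5.82-fold) and the xylosyltransferase XYLT1 (4.53-fold) were higher in kd.2. PLAT went from 2.15 ± 0.47 FPKM in the control to 0.50 ± 0.10 in kd.1 and 4.63 ± 0.18 in kd.2. In limma 3496 genes differed, 1289 higher and 2207 lower in kd.2, with adjusted p at or below 1.38e-05 for these 10. NCEH1 carries GAAGTCA, PLAT and NCCRP1 carry CTCAGAA, and XYLT1 carries GAAGTCA, CTCAGAA 2 times and TCAGAGT. Of the calls made in 1 line alone, 966 of 1535 in kd.1 and 1389 of 2479 in kd.2 also differed between the lines. The count was 5517 with only the 4 knockdown libraries, 5507 without either control and 1408 to 1811 without any 1 knockdown library, and with the length trend removed the split was 2232 higher and 2120 lower in kd.2.

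Between the lines, 13 of 25 G2 and mitosis genes were higher in kd.2 and 0 lower (14 higher adjusted over the list alone; median 0.24, adjusted p = 2.83e-06, and 0.5 with an estimated correlation). The YAP target genes had 5 of 12 higher and 1 lower in kd.2, also adjusted over the list alone (adjusted p = 0.00562, and 0.5 with an estimated correlation; 0.069 without the heptamer carriers). The interferon response genes had 6 of 15 lower and 0 higher (10 lower adjusted over the list alone; adjusted p = 0.0358, 0.5 with an estimated correlation and 0.0508 without kd.2 replicate 2). The NRF2 target genes had 10 of 17 lower and 0 higher (10 and 1 adjusted over the list alone; adjusted p = 0.0274, 0.754 with an estimated correlation and 0.128 with fry), a call lost without kd.1 replicate 1 (0.116), without kd.2 replicate 2 (0.0648) or without the heptamer carriers (0.069). The p53 target genes were not called between the lines (adjusted p = 0.797), with 5 higher and 5 lower, a median of -0.07, a mean of -0.02 and a test direction of up.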

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

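The tests of explanations in this part were chosen only after the gene-level result was seen, except that leaving out each library was chosen before the data were examined; for a single control library and for the control shRNA seed the prediction was written after the values it concerns. A tested difference between the knockdown lines singled out the following named genes, given as log2 of kd.2 over kd.1. Lower in kd.2 were SEPP1 (-3.51), CDKN1C (-3.38), AGR2 (-3.19), NCCRP1 (-2.85), FXYD3 (-2.63), TRIM31 (-2.56), STAMBP (-2.50), ESPN (-2.38), COL15A1 (-2.08), FZD10 (-1.92), KRT17 (-1.90), RGS19 (-1.75), ANXA10 (-1.60) and CRIP2 (-1.15). Higher in kd.2 were CCL2 (3.48), CD180 (2.99), PLAT (2.99), NCEH1 (2.54), XYLT1 (2.18), CPA4 (2.15), SAA1 (1.99), PLSCR4 (1.43), CALB2 (1.42), EREG (1.31) and EPGN (1.02). The same kind of difference was found in limma's camera for the G2 and mitosis genes (adjusted p = 2.83e-06), the YAP target genes (0.00562), the NRF2 target genes (0.0274) and the interferon response genes (0.0358); with an estimated correlation these were 0.5, 0.5, 0.754 and 0.5. In data outside the comparisons, 6 of the 360 tested features that the table names without a gene rose in both knockdown lines, and 14 fell in both.

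The many differences between the knockdown lines were weighed first. Windows of 50 neighbouring genes held 1.99% of the variance of called genes, which excludes copy number as the main cause. With the length trend removed 5.4% of the calls were lost. Removal also lowered the SD of the difference between the control duplicates from 0.2355 to 0.2036, and this spread enters the test. The share of lost calls therefore leans low. It argues against the trend as the cause of most calls but does not measure its part. The split of 1289 higher and 2207 lower in kd.2 did move without the trend, as given above. The trend is therefore not excluded as a cause of the excess of genes lower in kd.2. Among genes lower in kd.1, 26.3% carried GAAGTCA, 14.7 points above uncalled genes and between the bounds of 10 and 20 set beforehand, and the median shift was -0.074 with 1 site and -0.156 with more; most of these genes thus have no such site, and the part played by the sites, directly or through the genes they lower, cannot be told apart from other causes. Among genes lower in kd.2, 23.7% carried CTCAGAA, 6.7 points above uncalled genes and under the bound of 10. Most of these genes thus have no such site, so sites in the genes themselves are not the whole cause. The points in both lines are not corrected for UTR length, and effects passed on through other genes were not tested. ZNF281 was at the same level in both lines, so a different depth of knockdown was not seen, and each shRNA is 1 line, so effects of the shRNA and of the line cannot be separated.

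The heptamers were weighed next. GAAGTCA and CTCAGAA were picked as the lowest of all heptamers. That 0% of heptamers with the same bases reached a z as low was therefore fixed. The lowest of the 419 with the same bases stood at -6.4 in kd.1 and -4.2 in kd.2, against -11.66 and -11.16. This gap argues against base composition alone. The coding sequence of ZNF281, which both shRNAs target, holds GAAGTCA 1 time and CTCAGAA 4 times (2 of 2). If all heptamers were equally frequent and independent, it would hold both in 1.9% of cases. That assumption was not checked, so 1.9% is only a rough level. Seed matches of the ZNF281 shRNAs predicted that both would be held. The sequences of these shRNAs are not given in the sources used here, so a match to them was not tested. TCAGAGT, absent from that sequence, had a z of -0.86 between the lines. Of 629 heptamers with its bases 0 stood as high (3.58 in kd.1 and 2.68 in kd.2 at most). This too was fixed, as TCAGAGT was picked as the highest. GGCTAAT reached 7.23 between the control duplicates. Whether TCAGAGT belongs to the control shRNA cannot be told apart from a difference between the control libraries or an effect of ZNF281 itself. The control sequence is not given in the sources used here.

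The lower p53 target genes were weighed last. Their mean log2 change over both lines was -0.41 with 18 of 20 below 0. It was -0.40 without control replicate 2, the smaller change of the pair, and -0.40 with the length trend removed. In the 14 members without the heptamers it was -0.47, with all 14 below 0. These values argue against a single control library or the length trend as the cause. The 14 members were chosen for lacking the heptamers, so the absence of sites within them was fixed. Their lower levels show only that sites in the members themselves are not needed for the fall. This reading took the members as independent, although their estimated correlation was 0.102, so it is less certain than it appears. Effects passed on through other genes with sites were not tested. Both control libraries come from the same line, so a trait of that line or its shRNA was not tested either. No biological explanation was tested.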

How the results depend on the processing

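ZNF281 kept its direction in every setting and its call in all but the fold minimum of 2, which its change of 1.96-fold in kd.1 and 1.98-fold on average did not reach, none of the 427 named gene results and no list turned its sign with a call on either side, and pseudocounts of 1 and 0.01 ended none of those calls. Leaving out 1 library gave 1294 to 5531 genes changed by kd.1, 1282 to 6175 by kd.2, 1408 to 5507 differing between the lines, 1888 to 5864 on average over both shRNAs and 469 to 3552 changed the same way by both; 2 to 9 lists were called, and the correlation of fold changes ran from 0.336 to 0.6004. Without kd.1 replicate 1 these were 1336 for kd.1, 1811 between the lines, 2446 on average and 573 the same way; without kd.1 replicate 2, 1294, 1738, 2324 and 594. Without kd.2 replicate 1 they were 2007 for kd.1, 1282 for kd.2, 1408 between the lines, 1919 on average and 469 the same way; without kd.2 replicate 2, 2005, 1481, 1651, 1888 and 490. Without control replicate 1 they were 5531, 6175, 5507, 5864 and 3552, with 2 lists and a correlation of 0.6004; without control replicate 2, 5507 differed between the lines, 9 lists were called and the correlation was 0.336. A group of 1 library adds nothing to the estimate of spread. Without a control library that estimate rests on the knockdown lines alone. Their duplicates differed less (SD of the log2 difference 0.147 in kd.1 and 0.137 in kd.2, against 0.245 in the control). Counts without a control library therefore lean high. How far this accounts for the changes in count was not tested. With only the 4 libraries compared, 2015 genes changed in kd.1, 5517 differed between the lines and 836 changed the same way. Without a filter 909 changed the same way. With a fold change of at least 2, 167, 164, 238 and 68 genes were left for kd.1, kd.2, the difference and the average, and 30 the same way, by construction. With an estimated correlation 0 lists were called, and the mesenchymal and EMT genes lost their call at an estimate below the preset. That setting rests on 3 residual degrees of freedom and could hardly call any list. Fry passed every list call of camera except those of the NRF2 target genes and cytosolic ribosomal proteins. Splits moved by over 10 points with a common FPKM sum (1889 up and 847 down in kd.1, 2122 and 1339 in kd.2, 2224 and 1031 on average, 855 and 342 the same way), where most kd.2 calls were up instead of down (1705 and 2405 as deposited); by construction this scaling moved the median change by 0.078 in kd.1, 0.0987 in kd.2 and 0.0883 on average. They also moved with the length trend removed (2232 and 2120 between the lines, 1289 and 2207 as deposited); the cause was not tested. The replicate block left 2930, 3891, 3340, 3550 and 1274 genes and ended the kd.1 call of the replication-dependent histones (adjusted p = 0.0503); deviations with the same replicate number correlated at 0.183 between kd.1 and kd.2, 0.022 between kd.1 and control and -0.087 between kd.2 and control. The DESeq2 alternative was not run, as it needs counts. Uncalled values did turn sign without 1 control library, as for ESAM over both shRNAs (-0.44 to 0.07), FOXA1 over both (-0.22 to 0.03) and BMI1 in kd.1 (-0.14 to 0.49). Depth is unknown, so what it limits could not be told.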

Other observations

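All genes in this part were chosen after their values were seen, and no explanation was tested. SNAI2, a transcriptional repressor of the Snail family, rose from 1.21 FPKM in the control to 3.71 in kd.1 and fell to 0.79 in kd.2, a log2 difference between the lines of -2.09 (limma, adjusted p = 3.95e-05). CLDN7, a tight junction gene, stood at 14.3, 29.4 and 7.43 FPKM (difference -1.96, adjusted p = 1.31e-05), and the interferon-induced OAS1 at 43.3, 70.9 and 38.2 (-0.89, 4.34e-05). The interleukin genes IL1A and IL1B stood at 0.29 and 0.76 FPKM in the control, 1.11 and 1.45 in kd.1 and 0.18 and 0.16 in kd.2 (-2.13 and -2.60, adjusted p = 7.11e-05 and 5.8e-05). Among p53 targets outside the rule, BBC3 stood at 2.85, 1.35 and 1.5 FPKM.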
